A study of Rattus norvegicus with 12 samples.

How the data were processed

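DNA copy number was measured by array comparative genomic hybridisation, in which DNA of a tumour and DNA of a reference tissue carry different dyes and compete for the same probes. Each of 12 arrays held 1 lung adenocarcinoma of a female Wistar rat. Per the labels, tumour DNA came from frozen sections from which stained areas of adenocarcinoma had been scraped, and it carried Cy3. Ear skin DNA carried Cy5 as the reference. The labels do not say whether the skin came from the same rat, and no array had the dyes swapped. Groups were taken from the sample descriptions, with 3 tumours from unirradiated rats and 3 each from rats irradiated at 1, 5 or 15 weeks of age. The X-ray dose is labelled only as a range from 1 to 5 Gy, so dose was not analysed. The labels call the tumours individual adenocarcinomas but do not say that each came from a different rat.

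Per the submitters' processing notes, images were read with Agilent Feature Extraction 10.7.3.1. Per the file headers, the deposited processed intensity of each dye had been background-subtracted, spatially detrended and scaled linearly between dyes, with no lowess step. The deposited log10 ratio in the same files was Cy5 over Cy3 and served to check the sign. A matrix of log2 ratios by the authors was also deposited, and how it was normalized is not given in the sources used here. Its values ran as log2 of Cy5 over Cy3, the opposite sign to the one used here, with column medians of -0.02 to 0.06. Against the scanner values it had r of at least 0.99 on 9 arrays, and 0.917, 0.925 and 0.930 on 1-week tumour 2, 5-week tumour 2 and 15-week tumour 1. On those 3 arrays the difference varied along the chromosomes, and the correction behind it remains unknown.

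The value per probe was log2 of Cy3 over Cy5 processed intensity. Control spots and spots marked as outliers (104 to 332 of 99973 per array) were left out, spots of a probe were averaged, and each array was centred on its autosomal median. No loess or quantile step was applied. After this the modes of the arrays lay between -0.16 and 0.12, which centring on the mode subtracts. After this 95593 probes with a position in build rn4 remained, a median of 19.1 kb apart. Of these, 50189 carried a gene name, with 15122 different names, 9709 of which were also symbols in the RefSeq gene table given (assembly GRCr8, used for names only). In each channel of every array, 98.6% to 99.8% of spots were well above background. The number of arrays limits the precision of every comparison. Step noise, a robust spread of differences between neighbouring probes, was 0.13 to 0.23 on 11 arrays and 0.57 on 15-week tumour 1.

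Segments were found per chromosome by optimal partitioning with a penalty of 2 times the variance times the log of the number of probes, after pulling values beyond 3 noise units from a running median of 7 probes back to that limit. A segment of at least 5 probes with a mean of at least 0.2 in size was called. Calls are named Cy3-high or Cy3-low: with the dyes as labelled these are gains and losses in the tumour, and with the dyes reversed they would be losses and gains. The genome was divided into 2723 bins of 1 Mb with at least 5 probes on the autosomes and X. A bin took the call of over 50% of its probes. Recurrence was judged against 1000 rotations in which each tumour's calls were shifted around the genome independently, with the 95th percentile of the genome-wide maximum as the threshold. The same kind of rotations tested 8 gene lists in each direction, adjusted over 16 tests. In these tests a gene took the call of the 1 Mb bin that holds its middle probe. Each tumour was shifted separately, so regions shared by tumours were not kept together. A list with members in such a region can pass by their place alone, so list p-values may be too small. These rotations assume that calls of different arrays are independent apart from shared copy changes, so an array-wide bias of certain regions would count as recurrence.

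Differences between groups in the share of bins called and in the number of segments were tested by exact two-sided permutation tests, and relations with age by exact permutation of all pairings, where a resampled test had been planned. Bin means and gene means were tested with limma 3.58.1 in R 4.3.3, with 4 groups and adjustment by Benjamini-Hochberg at 0.05. A gene's value was the mean of its own probes, or of the 5 probes nearest its first probe where it had under 3 of its own, which makes the value one of the region. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used otherwise.

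The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists were lung cancer oncogenes (21 of 28 found on the array), lung tumour suppressors (25 of 28), DNA damage response genes (20 of 28), lung epithelial lineage genes (13 of 22), cell cycle and mitotic genes (15 of 22), EGFR, RAS and PI3K pathway genes (23 of 25), 19 lymphocyte antigen receptor names and 497 members of copy-variable gene families. The antigen receptor loci stood in for markers of other cell types, since lymphocytes lose DNA there. Braf, Myc, Pik3ca and Nkx2-1 are not analysed here. Some list members that the rule selects are not reported here, although they stay in all counts and tests. The rule named up to 25 list members called in at least 3 tumours, ranked by tumours and then by mean, the 10 most frequent recurrent regions with up to 3 list members or the 2 nearest genes, the 10 focal segments under 3 Mb with the largest means, and the 10 largest differences each way between irradiated and spontaneous tumours among listed genes. Other genes in the text were chosen after their values were seen, and are introduced as such.

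Alternatives covered the authors' deposited matrix, normexp on median and background median signals with an offset of 50 (mean signals were planned, and median signals were used), centring on the mode, a filter on dim probes, autosomes alone, other thresholds, penalties and segment sizes, other bin sizes, array weights, the replicate number or the slide as a block, and leaving out each tumour in turn. A correction for GC content was planned and not run, because no genome of build rn4 was at hand. Arrays shared 6 slides and 3 scan sessions, taken from the file headers.

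Segmentation with calls, recurrence and limma were tested on simulated data with noise independent between probes or bins. The rates below may therefore not hold where neighbouring bins move together. The list rotations, the permutation tests of share and segments, the age correlations and normexp were not simulated. On noise matched to the 11 less noisy arrays, 62.9% of segments of 10 probes with a mean of 0.3 were called, 99.2% with a mean of 0.5, and 100% of those of 50 probes. With the noise of 15-week tumour 1, 0 of 12 segments of 10 probes were called at either size and 75.0% of those of 50 probes at 0.5. A region planted in 11 of 12 arrays gave 7 of 7 bins past the recurrence threshold and 0 others. In limma on 2723 simulated bins, 32.8%, 91.0% and 100% of differences of 0.3, 0.6 and 1 between irradiated and spontaneous tumours were called, and over the 4 groups 14.9%, 73.1% and 98.5% were. For the 3 single groups against spontaneous tumours, 73.1% of differences of 0.6 were called in each. On 625 simulated listed genes, 26.9%, 89.6% and 100% were called. Each limma simulation changed 67, 67 and 66 features by 0.3, 0.6 and 1 at once. Between 7 and 12 unchanged features were called as well. The adjustment is stricter where fewer features differ, so these rates would then be lower.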

Results

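Copy number profiles of 12 rat lung adenocarcinomas were compared, 3 from unirradiated rats (spontaneous tumours) and 9 from rats that had received thoracic X-rays of 1 to 5 Gy, 3 each at 1, 5 and 15 weeks of age. The series addresses how age at exposure affects lung carcinogenesis. Its design text states that it cannot be known whether the tumours of irradiated rats were caused by radiation. Each tumour was hybridised on a single array against ear skin DNA, with 95593 probes a median of 19.1 kb apart. The arrays differed in quality, with step noise of 0.13 to 0.23 on 11 arrays and 0.57 on 15-week tumour 1. All values below are log2 of Cy3 (tumour, as labelled) over Cy5, the opposite sign to the deposited matrix. Segments are called Cy3-high or Cy3-low because other observations leave the dye direction open.

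The first question was which parts of the genome departed from the reference in these tumours, whatever their exposure. Chromosomes 5 and 15 were mostly Cy3-high in 6 of 12 tumours each, with means over the chromosome of 0.22 ± 0.16 and 0.24 ± 0.20 (SD, n = 12). Chromosomes 2 and 8 were mostly Cy3-high in 4 tumours each, with means of 0.16 ± 0.15 and 0.17 ± 0.18 (SD, n = 12). On the other side, chromosome 3 was mostly Cy3-low in 5 tumours, at -0.19 ± 0.10 (SD, n = 12), and chromosome 4 in 4, at -0.10 ± 0.18 (SD, n = 12). Over all tumours 29.6% ± 16.5 (SD, n = 12) of bins were called, 14.7% ± 11.7 (SD) Cy3-high and 14.9% ± 8.86 (SD) Cy3-low. Called bins were Cy3-high in 49.6% of cases.

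Recurrent Cy3-high calls lay mainly on chromosome 5, in 8 regions between 71000001 and 174000000 that made up 40 of the 47 recurrent bins. The most frequent region, 165000001 to 174000000, was called in 10 of 12 tumours at its peak bin (7 irradiated, 3 spontaneous). It had a mean of 0.33 ± 0.18 (SD, n = 12) and holds Mtor, a kinase of growth signalling. Bins from 150000001 to 156000000 were called in up to 9 tumours, at 0.31 ± 0.17 (SD, n = 12), and hold Arid1a, a subunit of a chromatin remodelling complex. A pair of further regions on the same chromosome were also called in up to 9 tumours, 157000001 to 162000000 near Ubxd3 and Pla2g2c at 0.33 ± 0.18 (SD, n = 12), and 79000001 to 83000000 near Dfnb31 and RGD1304595 at 0.30 ± 0.18 (SD, n = 12). The 47 bins were Cy3-high in more tumours than the rotation threshold of 7. Further such regions lay on chromosome 15, from 1 to 4000000 and from 10000001 to 12000000, each called in 8 tumours. The count of bins was sensitive to single tumours: without 1-week tumour 3, 5-week tumour 1 or 15-week tumour 3 it was 19, without 15-week tumour 2 it was 22, and without spontaneous tumour 3 it was 25. It was 22 with arrays centred on the mode and 20 or 11 with call thresholds of 0.15 or 0.3.

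Recurrent Cy3-low calls were shorter and lay on more chromosomes, several of them at clustered gene families. The bins from 70000001 to 72000000 on chromosome 3, which hold olfactory receptor genes such as Olr533, Olr535 and Olr536, were called in up to 11 of 12 tumours at -0.37 ± 0.20 (SD, n = 12). Other olfactory receptor clusters on that chromosome were called in up to 10 tumours each, 15000001 to 17000000 (Olr409, Olr410, Olr411) at -0.26 ± 0.11 (SD, n = 12) and 96000001 to 98000000 (Olr747, Olr752, Olr757) at -0.35 ± 0.18 (SD, n = 12). The bin from 87000001 to 88000000 on chromosome 18, nearest to FQ216879 and the adaptor gene Dok6, was called in 11 tumours at -0.40 ± 0.11 (SD, n = 12). It lies at the end of that chromosome, which had 88 bins. The first bins of chromosomes 7, 12 and 14 also passed the threshold, with 9 tumours each. Chromosome ends were not examined separately. A bin at 138000001 to 139000000 on chromosome 3 near P22k15 and a bin at 159000001 to 160000000 on chromosome 4 near the lectin genes Clec4a2 and Clec4a3 were called in 10 tumours each, at -0.34 ± 0.16 and -0.33 ± 0.16 (SD, n = 12). In all, 28 bins passed the threshold of 7 tumours. With 10000 rotations and another seed, 1.33% of rotations reached 8 tumours on the Cy3-high side and 4.32% on the Cy3-low side. The Cy3-low count was 14 after normexp, 9 with arrays centred on the mode, 15 at a call threshold of 0.3, 11 when segments under 1 Mb were dropped, 13 without the 3 arrays whose deposited values diverge from the scanner values and 5 within scan session 3. Leaving out single tumours gave 17 without spontaneous tumour 3, 1-week tumour 1 or 5-week tumour 2, and 16 without 5-week tumour 1.

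**Figure D1:**
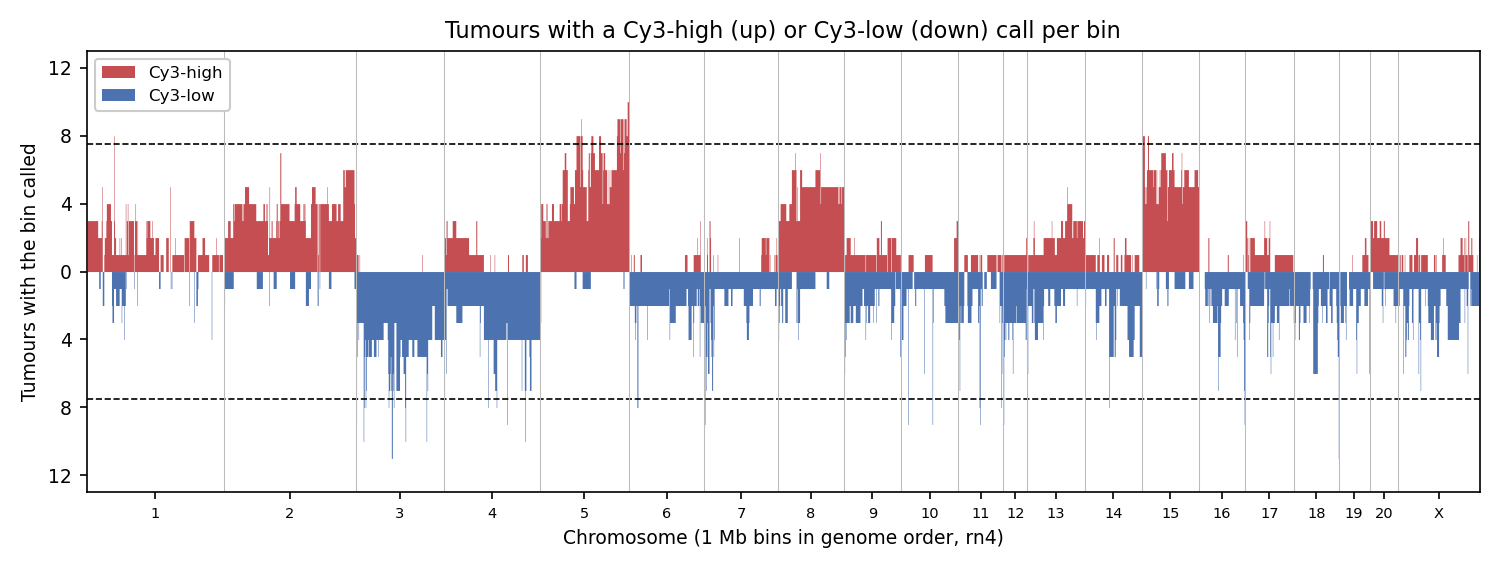
Number of the 12 tumours with a Cy3-high call (upward) or a Cy3-low call (downward) in each of 2723 bins of 1 Mb, in genome order; dashed lines lie just above the rotation threshold of 7 tumours. Broad Cy3-high stretches lie on chromosomes 2, 5, 8 and 15, and broad Cy3-low ones on chromosomes 3 and 4, with a highest Cy3-high count of 10 tumours on chromosome 5 and highest Cy3-low counts of 11 in single bins or short regions of chromosomes 3 and 18.

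Lung tumour suppressors lay in Cy3-high calls more often than the rotations gave. Of the gene and tumour pairs of this list, 22.7% were Cy3-high against 14.8% on average in the rotations (adjusted p = 0.0160, 25 members), and the mean of the list was above 0 in 11 of 12 tumours. In at least 3 tumours each, 12 members were Cy3-high and 4 were Cy3-low. These were, among members chosen after their values were seen, Arid1a (9 tumours, 0.33 ± 0.20 SD, from 1 probe of its own and its neighbours), the cyclin-dependent kinase inhibitor genes Cdkn2a and Cdkn2b (6 tumours each, 0.30 ± 0.24 and 0.33 ± 0.19 SD, 1 own probe each), Rb1, a brake on cell cycle entry (6 tumours, 0.25 ± 0.29 SD, 9 probes), and Fhit, a large gene at a fragile site (6 tumours, 0.28 ± 0.23 SD, 112 probes). The member with the most Cy3-low calls was Lrp1b (5 tumours, -0.22 ± 0.19 SD, 36 probes). Many of these genes share chromosomes 5, 8 and 15, so they are not independent observations. The rotations also shifted each tumour separately and did not keep regions shared by tumours together. The p-value may therefore be too small, as may those of the lists below.

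Genes of the lung epithelial lineage lay in Cy3-low calls in 21.8% of pairs against 14.9% in the rotations (adjusted p = 0.0480, 13 members), and the mean of the list was below 0 in 9 of 12 tumours. The call held under 9 of 13 other settings and was lost at a threshold of 0.3 (adjusted p = 0.0746), at a penalty of 4 (0.0533), with segments of at least 1 Mb (0.660) and within scan session 3 (0.192). It was also lost in 7 of 12 runs without a single tumour, namely without any of the spontaneous tumours, 1-week tumour 1, 5-week tumour 1 or 2, or 15-week tumour 3 (adjusted p from 0.0320 to 0.137 over the 12 runs). Members with Cy3-low calls, chosen after their values were seen, were the secretoglobin gene Scgb3a2 (6 tumours, -0.33 ± 0.12 SD), the transcription factor gene Foxa2 (5 tumours, -0.19 ± 0.11 SD) and the surfactant protein gene Sftpb (4 tumours, -0.13 ± 0.20 SD). The surfactant protein gene Sftpc went the other way and was Cy3-high in 6 tumours (0.31 ± 0.20 SD), as was Pdpn in 7 (0.18 ± 0.19 SD).

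Copy-variable gene families had the highest share of Cy3-low pairs, 29.9% against 15.0% in the rotations (adjusted p = 0.0160, from the smallest p that 1000 rotations can give), with a list mean below 0 in 11 of 12 tumours. In at least 3 tumours each, 277 of 497 members were Cy3-low and 113 were Cy3-high. All 25 genes that the rule for recurrent list members selected belonged to this list and were Cy3-low. Of them, 20 were olfactory receptor genes on chromosome 3, called in 10 or 11 tumours, with means from -0.53 ± 0.24 for Olr731 and -0.49 ± 0.29 for Olr561 to -0.26 ± 0.14 for Olr778 (SD, n = 12). The others, called in 9 tumours each, were Olr881 on chromosome 7 at -0.43 ± 0.20 (SD, n = 12), the natural killer cell receptor genes Klra5, Ly49i7 and Ly49s7 on chromosome 4 with means near -0.41, and the pheromone receptor gene Vom1r105 at -0.39 ± 0.16 (SD, n = 12). All but Vom1r105 (9 own probes) rest on 1 own probe and its neighbours, and probes of such families can bind several copies, so the values are uncertain for any single gene. Tumour counts of single genes also differ from the bin calls used for the pairs. The bin from 74000001 to 75000000, which holds Olr731, was Cy3-low in 8 tumours.

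The 5 remaining lists did not pass after adjustment in either direction. Cell cycle and mitotic genes were Cy3-high in 18.9% of pairs (adjusted p = 0.131), and EGFR, RAS and PI3K pathway genes in 18.5% (adjusted p = 0.120), with list means above 0 in 9 and 10 of 12 tumours. DNA damage response genes were Cy3-high in 16.7% and Cy3-low in 12.5% of pairs (adjusted p = 0.459 and 0.998). Lung cancer oncogenes were at 13.9% and 13.5% (adjusted p = 0.998 for both). Chosen after its values were seen, Egfr was Cy3-high in 1 and Cy3-low in 2. Lymphocyte antigen receptor loci, included as a sign of lymphocytes in the scraped tissue, were Cy3-low in 27.2% of pairs (adjusted p = 0.165), with a list mean below 0 in 8 of 12 tumours. The number of the 16 list tests that passed ranged from 2 to 5 over the settings. The suppressor and family calls held under all 13 settings and in all 12 runs without a single tumour, while the pathway list passed on the Cy3-high side after normexp, with arrays centred on the mode and at a threshold of 0.15 (adjusted p = 0.0440, 0.00799 and 0.00400), and the antigen receptor loci on the Cy3-low side at 0.15 alone (adjusted p = 0.0256).

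Focal segments, under 3 Mb with a mean of at least 0.5 in size, numbered 306 of 2299 called segments. The size is that of the mean itself and not of its difference from the flanks. Short pieces of broadly shifted chromosomes can therefore be among them. The 3 largest lay at the same site without named genes, 2144842 to 2626486 on chromosome 20, with means over the 6 probes of -1.80, -1.72 and -1.59 in 5-week tumour 1, spontaneous tumour 3 and 15-week tumour 3. Over the same 6 probes 7 other tumours had means of 2.56 to 3.16, and there the 4 probes from 2197451 to 2626486 formed a segment under the minimum of 5 probes, so it was not called. In 5-week tumours 2 and 3 the means were -0.48 and -0.64. The largest were ranked by segment mean after extreme values were pulled in, and the means given here are of the probes as measured. Of the 10 largest, 4 covered a site on chromosome 5 around 134250718 to 134511738 annotated with AY325175, with means of 1.02 in spontaneous tumour 3, 1.03 in 1-week tumour 2, 1.05 in 15-week tumour 2 and 0.95 in 1-week tumour 3. Over the 10 probes from 134250718 to 134528414, 10 of 12 tumours exceeded 0.5 and the lowest was at 0.27. In 5-week tumour 3, where 0.771% of the genome was called, the site was at 0.88, against -0.08 in the flanks of its segment there. The level was thus also high in a tumour that was hardly altered elsewhere, and its cause was not tested. Others were 4485064 to 4581494 on chromosome 7 (1.17 in spontaneous tumour 3, 5 probes) and 86977574 to 87051214 on chromosome 4 at AY383689 (-1.11 in 1-week tumour 2, 5 probes), where 9 tumours lay under -0.5. In these tumours the flanks were at -0.14 for the chromosome 7 segment and -0.53 for that on chromosome 4. A segment within Fhit, 16374634 to 16474013 on chromosome 15, reached 1.15 over 9 probes in 1-week tumour 3, against 0.56 in its flanks.

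**Figure D2:**
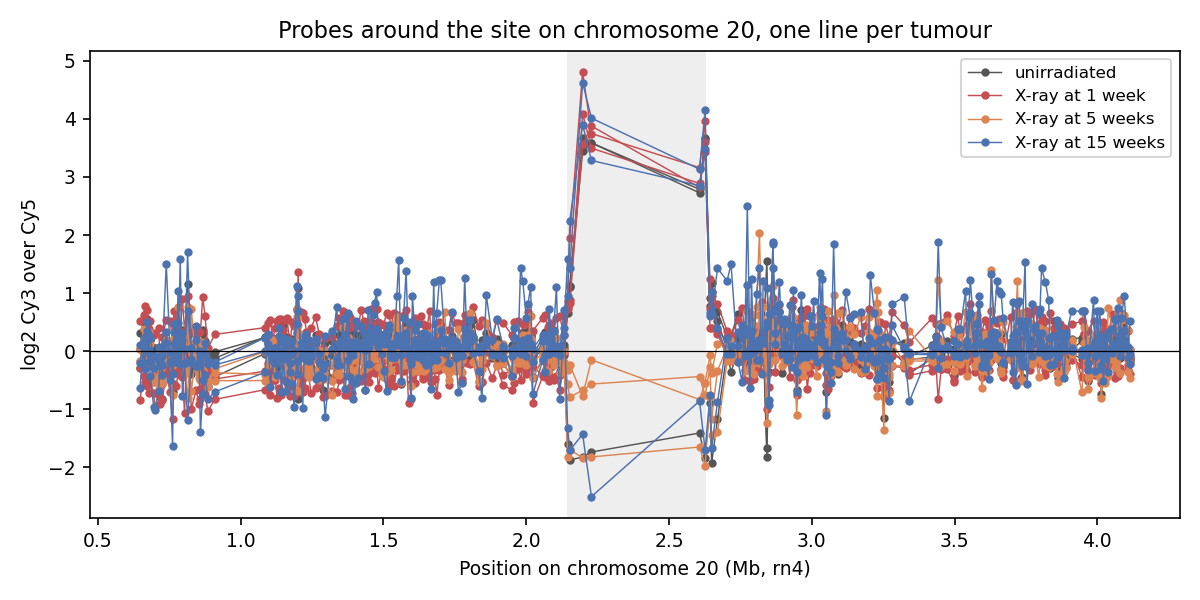
log2 of Cy3 over Cy5 per probe around the site on chromosome 20 (shaded, 2144842 to 2626486, position in Mb), a line per tumour coloured by group. Over the 6 shaded probes, 7 tumours have means of 2.56 to 3.16 and the other 5 lie below 0.

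The next question was whether tumours of irradiated rats differed from spontaneous ones in how much of the genome was altered. Called bins made up 27.5% ± 16.6 (SD, n = 9) of the genome in irradiated and 36.0% ± 17.5 (SD, n = 3) in spontaneous tumours, a difference of -8.51 points that was smaller than the spread between tumours (exact permutation p = 0.432, two-sided, 220 splits). The number of called segments was 178.2 ± 126.6 (SD, n = 9) against 231.7 ± 94.8 (SD, n = 3), a difference of -53.4 (exact permutation p = 0.582, two-sided). The direction was not settled: with a call threshold of 0.3 the difference in share was 7.26 points, and with the slide as a fixed block it was 19.2 points and 237.7 segments. The slide block links spontaneous with irradiated tumours through slide 5 alone, which held 1 tumour of each kind. Single tumours also moved it: the difference in share was -1.20 points without spontaneous tumour 1, -18.2 without spontaneous tumour 3 and -5.18 without 5-week tumour 3, and that in segments was 1.22 without spontaneous tumour 1, -82.8 without spontaneous tumour 2 and -92.3 without 1-week tumour 2. Of the single slides, only slide 5 held both kinds, with 52.2% in 1-week tumour 2 and 16.6% in spontaneous tumour 3, a difference of 35.5 points, and 308 more segments in the former. Within scan session 3, which held 5 irradiated and all 3 spontaneous tumours, the differences were -11.0 points and -40.3 segments.

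No bin and no listed gene passed the test for a difference between irradiated and spontaneous tumours. In the simulations, 32.8% of bins and 26.9% of listed genes with a difference of 0.3 were called, so differences of this size could be missed. Larger changes were planted beside them, and these rates would be lower where fewer features differ. With limma, 0 of 2723 bins passed at an adjusted p of 0.05 and 36 had an unadjusted p under 0.05 (smallest adjusted p = 0.980). Among listed genes, adjusted over the list alone, 0 of 625 passed and 1 had an unadjusted p under 0.05 (smallest adjusted p = 1.00). The largest positive difference was that of the immunoglobulin heavy chain name BC091247, at 0.33 ± 0.13 (SE), with means of -0.04 in irradiated and -0.37 in spontaneous tumours. It was followed by the growth factor receptor gene Fgfr3 at 0.33 ± 0.17 (SE), the water channel gene Aqp5 at 0.31 ± 0.17 (SE) and Cdk4 at 0.29 ± 0.17 (SE). Cyp2d3, Tsc2, Defb27, Erbb3 and BC087137 had differences of 0.25 to 0.26, the last of which was -0.02 after normexp. The largest negative differences were those of the immunoglobulin kappa name M87784 at -0.27 ± 0.19 (SE) and Olr1612 at -0.25 ± 0.16 (SE). Olr801, Klra22, Olr136, Defb2, Defb10, Olr1610 and Olr379 lay between -0.23 and -0.21. Among the genes named here, BC091247, BC087137, M87784, Tsc2 and Erbb3 had at least 3 probes of their own, and the others rest on neighbouring probes too. Many of these differences moved by over 1.5 times without a single tumour. Without spontaneous tumour 3, BC091247 was at 0.16, BC087137 at 0.45 and Klra22 at -0.38. Without spontaneous tumour 1, Aqp5 was at 0.19, Cdk4 at 0.16, Cyp2d3 at 0.13, BC087137 at 0.10 and Erbb3 at 0.08. Without spontaneous tumour 2, M87784 was at -0.16, Olr1612 and Klra22 at -0.11 and Olr1610 at -0.09. Without 15-week tumour 1, Tsc2 and Defb27 were at 0.15, and without 5-week tumour 2, Defb2 and Defb10 were at -0.13.

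As groups, the lists also did not pass the test for a difference between irradiated and spontaneous tumours. The lineage genes had the largest mean difference, 0.10, with 10 of 13 members higher in irradiated tumours (exact permutation p = 0.0909, adjusted p = 0.611 over 8 lists). Oncogenes differed by 0.08 (14 of 21 members higher, adjusted p = 0.611), tumour suppressors by 0.03 (12 of 25, adjusted p = 0.701) and DNA damage response genes by 0.04 (15 of 20, adjusted p = 0.611). Cell cycle genes differed by 0.05 and pathway genes by 0.05 (adjusted p = 0.611 for both), antigen receptor loci by 0.02 (adjusted p = 0.818) and gene families by -0.03 (adjusted p = 0.701). Within scan session 3 the differences were 0.07 for lineage genes, 0.03 for DNA damage response and cell cycle genes, 0.02 for oncogenes and pathway genes, 0.004 for suppressors, 0.05 for antigen receptor loci and 0.01 for gene families, the last with the reverse of the pooled sign. Within slide 5 they were 0.15 for lineage, 0.13 for pathway, 0.10 for cell cycle genes and 0.02 for oncogenes, -0.05 for gene families, and the reverse of the pooled sign for antigen receptor loci (-0.37), DNA damage response genes (-0.03) and suppressors (-0.004).

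The last question was whether age at exposure made a difference. Tumours of rats irradiated at 1 week had 45.4% ± 10.5 of the genome altered, at 5 weeks 12.9% ± 10.5 and at 15 weeks 24.1% ± 8.59 (SD, n = 3 each), beside 36.0% ± 17.5 in spontaneous tumours (SD, n = 3). The place of the 15-week group depended on the values used, since its mean was 36.7% ± 4.23 with arrays centred on the mode, beside 39.5% ± 20.3 in spontaneous tumours, and 16.6% ± 3.85 in the authors' matrix, beside 36.6% ± 18.1 (SD, n = 3 each). Single tumours ranged from 0.771% in 5-week tumour 3 to 52.2% in 1-week tumour 2. Across the 4 groups the differences did not pass the test (F = 3.98, exact permutation p = 0.0624 over 369600 assignments). They did pass under 5 other settings and without spontaneous tumour 3 (F = 7.93, exact permutation p = 0.0186). F was lower without the 3 arrays whose deposited values diverge (2.47, exact permutation p = 0.210) and within scan session 3 (2.55, exact permutation p = 0.185). Of the pairs of groups, 5 weeks and 1 week differed most, by -32.4 points, with an exact permutation p of 0.10, the smallest that 3 against 3 tumours allow (adjusted p = 0.400 over 12 comparisons). Within slide 6 a 1-week tumour had 33.3% and a 5-week tumour 0.771%, and within slide 3 a 1-week tumour had 50.6% and 15-week tumour 1, the noisiest array, 33.9%, which was 12.1% in the authors' matrix.

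Called segments numbered 288 ± 174.6 in 1-week, 120.7 ± 80.5 in 5-week and 126 ± 2 in 15-week tumours (SD, n = 3 each). The 1-week mean rested on tumour 2 with 489 segments and was 187.5 without it. The difference from 1 week was -167.3 segments at 5 weeks (exact permutation p = 0.30, adjusted p = 0.450) and -162 at 15 weeks (exact permutation p = 0.10, adjusted p = 0.400). From spontaneous tumours, 15-week tumours differed by -105.7 segments (exact permutation p = 0.10, adjusted p = 0.400), 5-week tumours by -111 (0.30, adjusted p = 0.450) and 1-week tumours by 56.3 (0.60, adjusted p = 0.655). The share altered had no relation to age that passed the test over the 9 irradiated tumours, with a Spearman rho of -0.47 (exact permutation p = 0.218) and a Pearson r of -0.38 (exact permutation p = 0.320). Leaving out single tumours gave a rho from -0.69 to -0.28 (exact permutation p from 0.0679 to 0.489). The 3 tumours at 15 weeks tie as the farthest from the median age. Without tumours 1 and 2 of them, rho was -0.69 and r -0.51 (exact permutation p = 0.114 and 0.279), without 1 and 3 they were -0.85 and -0.55 (0.0286 and 0.179), and without 2 and 3 they were -0.50 and -0.27 (0.257 and 0.607), so the result rested on which tumours were left out. Within scan session 3, which held all 4 groups, the means were 42.7% at 1 week (n = 2), 0.771% at 5 weeks (n = 1) and 19.2% at 15 weeks (n = 2).

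**Figure D3:**
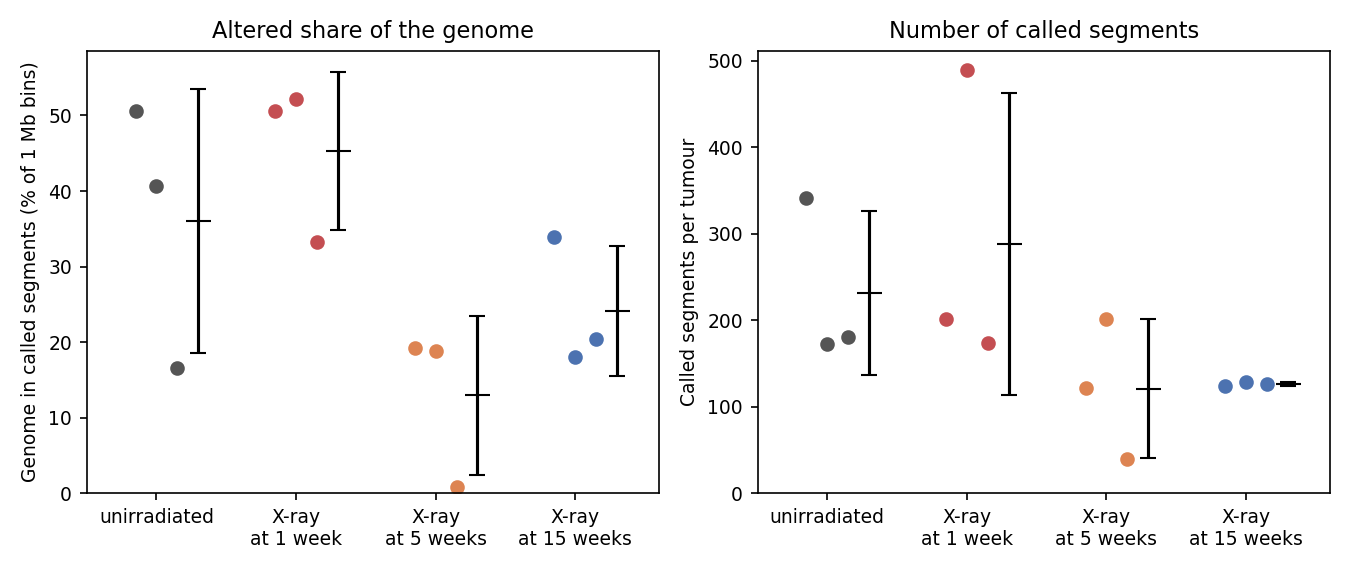
Percent of 1 Mb bins in called segments (left) and number of called segments (right) for each tumour, by group; points are tumours and the bars beside them give the group mean and SD (n = 3). The 1-week tumours lie between 33.3% and 52.2% and the 5-week tumours between 0.771% and 19.2%, while spontaneous tumours span 16.6% to 50.6%.

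Bin by bin, no age group had a bin that passed the test against the spontaneous tumours. For single groups, 14.9% to 16.4% of simulated differences of 0.3 were called, so differences of this size could be missed. These rates would also be lower where fewer bins differ. With limma, 0 of 2723 bins passed for 1 week (192 with an unadjusted p under 0.05, smallest adjusted p = 0.639), 0 for 5 weeks (27, smallest adjusted p = 0.843) and 0 for 15 weeks (84, smallest adjusted p = 0.906). In the test among the 4 groups 0 bins passed and 178 had an unadjusted p under 0.05 (smallest adjusted p = 0.548). Array quality weights gave 388 bins in this last test, and the slide as a fixed block gave 16 bins at 15 weeks. That block links spontaneous with irradiated tumours through slide 5 alone.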

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

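The tests of copy loss and of a dye or composition bias at the gene families, of the trend in 3 arrays and of other groupings of the tumours were chosen after the results were seen, as were the reading of the receptor loci against the families and the tally in Fhit, Dlg2 and Fat1. Of the tumours, 2 stood far from the other irradiated ones by the gap to the nearest value: 1-week tumour 2 with 489 called segments, and 15-week tumour 1 with step noise of 0.567. Both were found among 5 measures in 9 tumours. For a single measure chance flags about 1 in 20 such groups, and over 5 measures it does so more often.

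The first pattern is the direction of the ratio: tumour suppressors such as Cdkn2a, Rb1, Fhit and Arid1a lay in Cy3-high calls, where loss would be the textbook change, and a candidate explanation is that the dyes are reversed in the labels, in which case antigen receptor loci, where lymphocytes have lost DNA, would lie above their flanks in Cy3 over Cy5. The median over 12 tumours was -0.059 (standard error 0.032, above 0 in 2 tumours) and -0.054 in the authors' matrix (standard error 0.010, above 0 in 0 tumours), which met the value written beforehand as speaking against reversal. That bound was wrong, because clustered gene families in general lay below their flanks by a median of -0.060 (-0.059 in the authors' matrix), and the receptor loci less the families were at 0.011 ± 0.023 (SE, above 0 in 7 of 12 tumours), or 0.006 ± 0.007 in the authors' matrix (8 of 12). The loci did not move together, with 0 of 12 tumours above the flank at the lambda locus of 9 probes on chromosome 11 (median -0.25), 10 at the locus on chromosome 4 (0.03), 8 on chromosome 15 (0.01) and 5 on chromosome 6 (-0.03). The immunoglobulin kappa name M87784, elsewhere on chromosome 4, was not within these 4 loci. Among 8 short segments in 15 large genes at fragile sites, 0 lay at least 0.2 above their flanks and 1 lay below (exact two-sided binomial p = 1), but this leaves out Fhit, Dlg2 and Fat1, which had been seen and where 6 of 9 short segments lay at least 0.2 above and 0 below, the way reversal would give, so the direction stays open, and no biological explanation for it was tested.

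The second pattern is the low ratio at clustered gene families such as the olfactory receptors of chromosome 3. Copy loss in the tumours stays open: in 5-week tumour 3, where 0.771% of the genome was called, the families minus their flanks were at -0.041 ± 0.012 (SE over 78 clusters). This met the bound written as speaking against copy loss. That bound was then set aside, because a single tumour cannot exclude it and no other tumour was so little altered. A bias of these clusters by dye or base composition needs the same sign on every array, and 12 of 12 arrays had it, from -0.122 to -0.040. That outcome rests on the choice of members, since the test was first run on 36 members in 19 clusters, where 10 of 12 tumours lay below 0 and nothing was decided, and was widened to all 497 members after that was seen. Inherited copy differences between tumour and reference rats stay open, since the 36 members varied 1.14 times as much between tumours as other genes, between the bounds set for either answer.

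The third pattern is the share of the genome altered by age at exposure, 45.4% at 1 week against 12.9% at 5 weeks. For array noise, share and step noise had a Spearman rho of -0.116 over 12 arrays (permutation p = 0.718) and a Pearson r of 0.001 (permutation p = 0.998). Without the 2 arrays farthest in noise they were -0.140 and -0.243 (permutation p = 0.699 and 0.496). The rho met the value written beforehand as speaking against noise. It cannot decide the contrast of 1 with 5 weeks, where noise and group go together, so noise stays open. Step noise was 0.156 to 0.178 at 1 week and 0.180 to 0.234 at 5 weeks. The trend along the genome in the 3 arrays whose deposited values diverge from the scanner values is argued against as the whole cause. Without them the difference kept 98.5% of its size (32.4 and 31.9 points). Tumour cell content and dose stay open and untested. Slide and scan session stay open too: 5-week tumours 1 and 2 were the only arrays of slide 2 and of scan session 1. A biological difference by age also stays open. The test over the 4 groups (exact permutation p = 0.0624) includes spontaneous tumours. The rank correlation (exact permutation p = 0.218) sees only a steady trend with age. No test over the 3 exposure ages together was run.

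For the counts of differing bins and genes by limma, other groupings of the tumours were drawn. As every real count was 0 (36 bins at an unadjusted p under 0.05 between irradiated and spontaneous tumours, 178 among the 4 groups, 1 listed gene), every split is as large by construction, and the splits say nothing about chance. Between irradiated and spontaneous tumours 100 of 100 splits gave as many bins, with a highest other count of 0. Among the 4 groups 100 of 100 did, and the highest other count was 307 bins. Neighbouring bins move together, and whether this split follows a structure of the samples was not tested. For listed genes the real count was 0, 100 of 100 splits were as large, and the highest other was 25. For each age group against spontaneous tumours, the real count was 0 (192, 27 and 84 bins unadjusted at 1, 5 and 15 weeks), all 10 of 10 splits gave as many with a highest other of 0, and 10 splits are too few for a share under 0.05.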

How the results depend on the processing

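Leaving out the 3 divergent arrays, using scan session 3 alone, the slide as a fixed block and 10000 rotations were chosen after seeing the data. Of all values recomputed for the comparisons, 307 kept their direction and their side of the threshold, 19 counts moved by over 1.5 times, 8 newly passed and 4 reversed; of 45 values of named genes, 311 of 315 recomputations did, and BC087137 reversed to -0.0186 after normexp. The cause of these changes was not tested.

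The share altered, irradiated minus spontaneous, became 7.26 at a threshold of 0.3, -3.69 at 0.15 and 19.2 with the slide block. Without single tumours it ran from -18.2 to -1.20. The slide block rests on slide 5 alone for spontaneous against irradiated tumours. The difference in segments became 237.7 with the slide block, -104.2 with the authors' matrix and -100 without the 3 divergent arrays. It was -3.78 after normexp, -1.67 at a threshold of 0.3, -11.3 at a penalty of 4 and -13.1 with segments of at least 1 Mb. Without single tumours it ran from -92.3 to 1.22. The F over 4 groups was 5.24 with the authors' matrix, 5.90 after normexp, 12.95 at 0.3, 5.08 at a penalty of 4 and 5.27 with a threshold per array (exact permutation p = 0.0447, 0.0166, 0.00461, 0.0432 and 0.0464), and 2.64 to 7.93 without single tumours.

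Recurrent Cy3-high bins numbered 22 by mode, 20 at 0.15, 11 at 0.3 and 19 to 55 without single tumours. Cy3-low bins numbered 14 after normexp, 9 by mode, 15 at 0.3, 11 with segments of at least 1 Mb, 13 without the 3 arrays, 5 in session 3 and 16 to 28 without single tumours. Lists passing numbered 5 at 0.15, 4 after normexp and by mode, 2 at 0.3, at a penalty of 4, with segments of at least 1 Mb and in session 3, and 2 to 3 without single tumours; the list that lost its call was in each case the lineage genes. Differing bins numbered 388 among the groups with array weights (803 unadjusted) and 16 at 15 weeks with the slide block; without single tumours all counts of differing bins and genes were 0 (limma; unadjusted 6 to 122 bins for irradiated minus spontaneous and 80 to 371 among the groups).

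Replicate numbers are shared by the groups but do not pair the samples: same-numbered tumours correlated at a mean of -0.037, 6 of 18 pairs over 0.1, and 4 of 12 arrays correlated best with their own number. With the replicate block all counts of differing bins and genes stayed at 0 (limma; unadjusted 17 bins for irradiated minus spontaneous, 103 among the groups, 180, 8 and 68 at 1, 5 and 15 weeks, 1 listed gene) and the share differed by -8.51 (exact permutation p = 0.406). The slide as a random block had a correlation of 0.099. The GC correction was not run. Over 98% of spots were well above background, so background limited few probes.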

Other observations

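The test of copy changes at the chromosome 20 site was chosen after its values were seen, and the search for other such sites was written before its result. The genes in this paragraph and the next were chosen after their values were seen. A pair of immunoglobulin heavy chain names on chromosome 6 departed from each other: AJ286177 had a mean of 0.63 ± 0.21 (SD, n = 12), while AM293765, on the same chromosome, had -0.25 ± 0.21 (SD, n = 12). The lambda light chain name DQ394091 on chromosome 11 was Cy3-low in 8 of 12 tumours at -0.36 ± 0.14 (SD, n = 12), and BC099225, at the T cell receptor locus of chromosome 15, was Cy3-high in 5 at 0.22 ± 0.21 (SD, n = 12).

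Of the pathway genes not named so far, Spry2, an inhibitor of growth factor signalling on chromosome 15, was Cy3-high in 6 tumours at 0.35 ± 0.20 (SD, n = 12), and Pik3cb, a kinase subunit on chromosome 8, in 5 at 0.29 ± 0.26 (SD, n = 12). The cell cycle genes Cdc20 on chromosome 5 and Ccnb2 on chromosome 8 were Cy3-high in 7 and 6 tumours, at 0.33 ± 0.21 and 0.30 ± 0.21 (SD, n = 12). On chromosome 3, Tsc1 had a mean of -0.38 ± 0.28 (SD, n = 12) over 3 probes, with a Cy3-low call in 3 tumours and a Cy3-high call in 1.

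The site at 2144842 to 2626486 on chromosome 20 took values of 2.56 to 3.16 in 7 tumours and -1.59 to -1.80 in 3. All 1-week tumours were among the high ones, and all 5-week tumours lay below 0, a grouping that was not tested. Copy changes of the tumours against DNA of the same rat were tested by values beyond 1.5, and 3 tumours lay on the rarer side. This met the bound written as speaking against such copy changes. That bound was then set aside, since losses in some tumours and amplification in others would also give both signs. The test therefore does not decide. A hypothesis is that tumour and reference DNA came from different rats that differ at this site. A search for other sites of at least 3 probes with means beyond 1 in both directions found 1 (99837643 to 99880563 on chromosome 4, 1.26 in 15-week tumour 2 and -1.03 in 1-week tumour 3), fewer than the 3 set for the hypothesis and more than the 0 set against it, so it stays open. That other site lies near the immunoglobulin kappa name M87784 (100386064 to 100457238), and lymphocytes lose DNA at antigen receptor loci.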
